A study of Caenorhabditis elegans with 7 samples.

How the data were processed

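Gene expression was measured on Affymetrix arrays of the Caenorhabditis elegans genome in 4 samples of DD motor neurons and 3 samples of all cells, each from first-stage (L1) larvae that had hatched without food and were arrested in growth. Per the labels, RNA was amplified from a few nanograms of total RNA with a NuGEN kit made for small inputs before biotin labelling, in both groups. Groups and replicate numbers were taken from the sample titles, 1 array per sample. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The DD samples came from a strain with an mCherry reporter driven by the ttr-39 promoter and a GFP reporter driven by the ttx-3 promoter, and the all-cell samples from the wild-type strain N2. Strain and the sort for the reporter therefore changed together with cell type in every array. Whether the all-cell samples were dissociated or passed through the sorter was not given in the sources used here, and no batch or scan date was given in the sources used here. One characteristics label of the DD samples names GFP as the label, while the series design names mCherry as the sorted reporter, which was taken as correct.

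Per the labels, the authors made the deposited log2 values with RMA, a procedure that corrects the background, normalizes between arrays and summarises the probes of each probe set. The version, the software and the probe set definition were not given in the sources used here. They carry no detection call or background level, so the fold of a probe set that is dim in one group is not exact. The values cover 22625 probe sets, and the array medians lay between 5.21 and 5.38 (log2). The authors also deposited a table of 236 probe sets higher in DD neurons. Per the file headers, that table gives for each probe set a score, its numerator on the log2 scale and its denominator, a fold change as a linear ratio, and a q-value in percent, with a false discovery rate of 5.03% for the whole list. The name of the program behind it was not given in the sources used here. The authors' log2 differences equal the differences of the group means of the value table, with a largest deviation of 6.7e-15, so no other filter or scale lay between the tables. Their score was rebuilt as that difference over the pooled standard error plus a constant of 0.00307. A score of at least 2.59 together with at least 2-fold gave exactly the 236 listed probe sets, which was checked because the selection sets which genes can be named here.

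From the values, differences between the groups were tested with limma 3.58.1 (lmFit and eBayes in R 4.3.3) on all 7 arrays without covariates, after 77 array controls were left out, which left 22548 probe sets. The moderated test had 5 residual and 3.13 prior degrees of freedom. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Folds are given with the log2 difference and its standard error (SE), and levels as mean and standard deviation (SD) of the log2 values. On simulated arrays for the comparison of DD neurons with all cells, 10 runs with 200 changed probe sets each, limma recovered 27.6% of 2-fold, 77.8% of 4-fold, 92.8% of 8-fold and 97.6% of 16-fold changes, and 4.33% of its calls were false. The number of arrays limits the precision, and the smallest p that an exact permutation of 4 against 3 arrays can give is 0.0286. Other tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

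Gene names came only from the authors' deposited table, which pairs 222 of its 236 probe sets with 201 genes. Of these, 198 were matched to the RefSeq gene table of the assembly WBcel235 by name or sequence name, and 36 have a newer symbol there, which is given beside the older one. All other probe sets are unnamed here. Every named gene was therefore selected by the authors as higher in DD neurons, and no gene lower in DD neurons could be named. Where a gene had several probe sets, those not marked as matching several transcripts came first, and then the one with the highest mean over the 7 arrays.

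The rule for named genes, the gene lists, the tests and most alternatives were fixed before the data were examined. The rule took the 12 called genes with the largest fold and the 6 with the smallest adjusted p in each direction, among genes with every array of one group above every array of the other for the folds. It also took all measured members of the lists of GABA D-type identity and DD remodelling. From every other list it took the 3 called members with the largest fold, or the member with the highest mean level where none was called. It gave 29 genes. Another 44 genes named in the text were chosen after their values were seen. Of the 28 lists, 12 held no gene that could be named: GABA receptors, DEG/ENaC channels, innexins, cholinergic markers, other neurotransmitter classes, AIY, touch receptor and ciliated neuron markers, glia, coelomocyte and excretory cells, ribosomal proteins, and immediate early genes. The 6 lists with at least 3 named genes were tested with limma's camera against the other named genes, with a preset correlation of 0.01 and with an estimated one, in place of the test against all genes on the array that had been planned. The alternatives were eBayes with trend and robust settings, the dimmest 30% of probe sets dropped, another quantile normalization, scaling to the 75th percentile, array weights, a replicate block, each array left out, only probe sets not marked as matching several transcripts, Welch's test, a minimum of 1.5-fold, an adjusted p under 0.01, limma's fry, the mean of a gene's probe sets, and genes shared between lists left out. The authors' score was added after the data were seen. Scaling to ribosomal proteins was not run, since none could be named.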

Results

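The data compared gene expression in DD neurons with that of all cells in L1 larvae of Caenorhabditis elegans. DD neurons are GABAergic motor neurons of the ventral cord that later rewire their synapses. They were isolated by fluorescence-activated sorting, and the reference was RNA of all cells from a matched population, for which the labels give no sort or dissociation step. There were 4 arrays of DD neurons and 3 of all cells, with 22548 probe sets tested on each. The arrays were alike in overall profile, with a correlation across probe sets of 0.957 to 0.974 between DD arrays, 0.966 to 0.975 between all-cell arrays and 0.936 to 0.971 between groups. Probe sets are not independent replicates, so these correlations only describe the arrays. The first principal component held 36.8% of the variance and had positive values for all 4 DD arrays and negative values for all 3 all-cell arrays. DD replicate 1 had the lowest mean correlation with its own group, 0.960. The 77 array controls, which include probe sets for worm genes such as actin, had a median log2 difference of 0.34 between DD neurons and all cells. For the tested probe sets it was 0.06.

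Named genes that define GABAergic D-type motor neurons were higher in DD neurons. By 1 probe set per gene, the folds were 5.69 to 11.2 for the 6 that passed the test. The transcripts of unc-25, the enzyme that makes GABA, were 8.32-fold higher (log2 difference 3.06 ± 0.22 SE, limma adjusted p = 0.00544), at 11.29 ± 0.30 (SD, n = 4) in DD neurons and 8.23 ± 0.29 (SD, n = 3) in all cells. The vesicular GABA transporter gene unc-47 was 5.79-fold higher (2.53 ± 0.23, adjusted p = 0.00937), and unc-46, which sorts that transporter to synaptic vesicles, was 7.54-fold higher (2.92 ± 0.27, adjusted p = 0.00937). The homeodomain transcription factor gene unc-30, which specifies the D-type fate, was 9.33-fold higher (3.22 ± 0.31, adjusted p = 0.00937). The gene ttr-39, whose promoter drove the sorted reporter, was 11.2-fold higher (3.48 ± 0.26, adjusted p = 0.00544). The largest fold of all belonged to unc-10, the RIM protein of the presynaptic active zone, at 84.4-fold. It rests on 1 named probe set, whose all-cell level of 5.10 lay below the medians of the all-cell arrays (5.33 to 5.38). With no background level given, this fold is not exact, nor is that of unc-47, whose all-cell level was 4.67. High unc-10 expression could not be told apart from unc-10 sequence carried by the transgene.

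**Figure D1:**
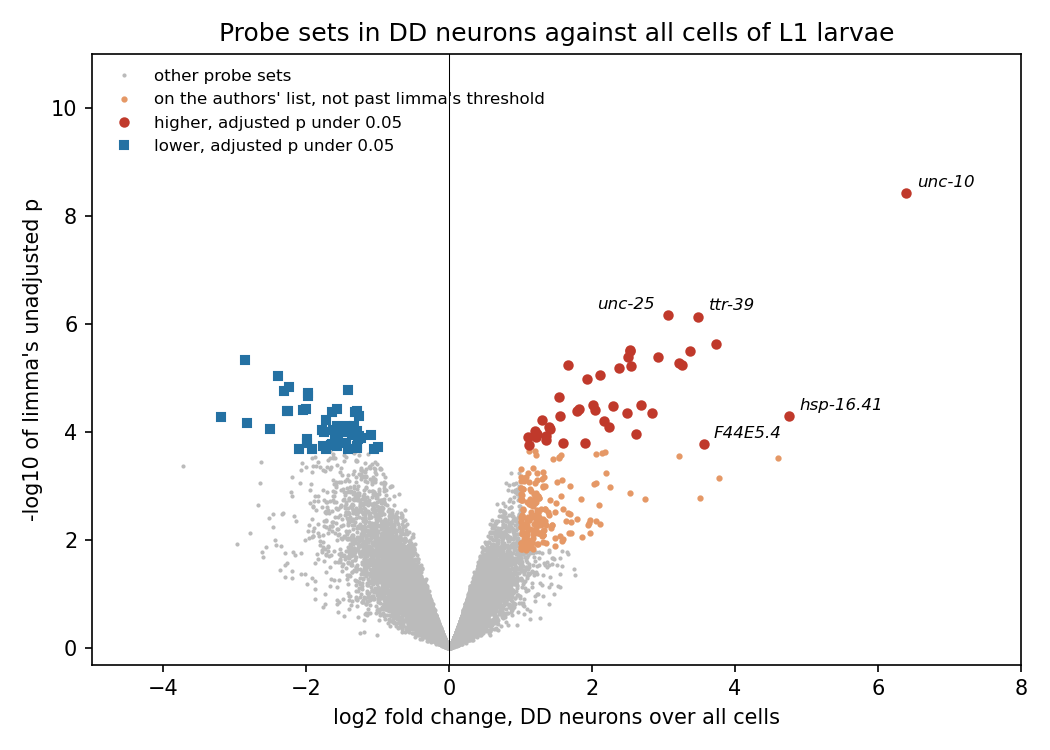
Each point is a probe set, placed by its log2 fold change in DD neurons over all cells (x axis) and the -log10 of limma's unadjusted p (y axis), with 4 DD and 3 all-cell arrays. The 43 called higher probe sets (red circles) and 51 called lower ones (blue squares) are marked, and unc-10 lies apart from the rest at a log2 fold of 6.40.

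In all, 43 probe sets for 39 genes were higher in DD neurons at an adjusted p under 0.05, with folds of 2.15 to 84.4, and 51 probe sets were lower, with folds of 2.00 to 9.11. Each of these probe sets had every array of one group above every array of the other. Over all probe sets, 1573 were separated in this way with DD neurons higher and 1497 with DD neurons lower, where chance gives 2.86% or 644 in each direction. At an unadjusted p under 0.05 there were 1369 higher and 2096 lower probe sets. All 43 called higher probe sets were on the authors' deposited list of 236, and all 236 had an unadjusted p under 0.05, with adjusted p up to 0.224. Both selections used the same arrays and similar scores, so this overlap is not independent evidence. The called lower probe sets could not be named here. The largest drop among them was 9.11-fold (log2 -3.19 ± 0.41 SE, adjusted p = 0.027). Without DD replicate 1, 2, 3 or 4 the higher count was 6, 15, 18 or 23 and the lower count 0, 2, 1 or 10, and without all cells replicate 1, 2 or 3 it was 21, 13 or 18 higher and 39, 5 or 7 lower (limma, with 1211 higher and 1779 lower at an unadjusted p under 0.05 without DD replicate 1). The genes unc-10, ttr-39, unc-25, oig-1 and, by 1 of its 2 probe sets, unc-30 stayed called whichever array was left out. Strain and cell type changed together, as did the sort for the reporter, and no array separates them.

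Of the 13 genes on the D-type identity list, 7 could be named, and 6 of these passed over all probe sets. The rest had no named probe set on the authors' list of higher probe sets. Because the authors chose all named genes as higher on these arrays, such counts are not independent evidence of direction, here or in any list. Adjusted over the list alone, all named members of every list pass, 7 of 7 here, but their selection fixed that outcome, since all 236 listed probe sets have an unadjusted p under 0.05. The gene outside the threshold was alr-1, an Aristaless-type homeobox gene, with a log2 difference of 1.51 ± 0.29 and an adjusted p of 0.0876. In the remodelling list of 22 genes, 2 could be named and both were higher. These were unc-30 and oig-1, which encodes a small immunoglobulin-domain protein that restrains DD remodelling and was 5.69-fold higher (2.51 ± 0.23, adjusted p = 0.00937). The probe sets of unc-30 ranged from 3.22 to 3.37 and those of unc-46 from 2.92 to 3.73, all called. The median log2 difference of the identity genes was 2.92, against 1.24 for the other named genes (camera adjusted p = 5.85e-09 with the preset correlation of 0.01). The correlation estimated for these genes was 0.40, far above the preset one. With it the camera adjusted p was 0.0909, so camera did not establish the difference. Without DD replicate 1, 3 of the 7 genes passed the threshold.

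**Figure D2:**
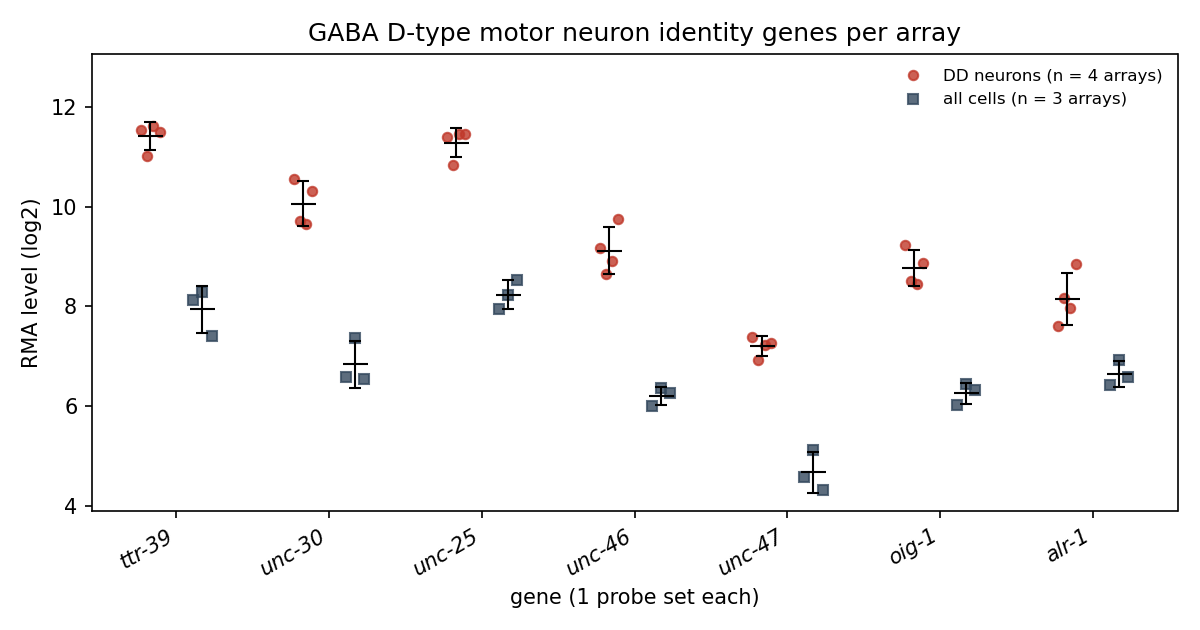
RMA levels (log2, y axis) of the 7 named D-type identity genes (x axis) on each DD array (red circles, n = 4) and all-cell array (dark squares, n = 3), with horizontal bars for the mean and whiskers for 1 SD. For every gene all 4 DD arrays lie above all 3 all-cell arrays, with log2 differences from 1.51 for alr-1 to 3.48 for ttr-39.

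For the synapse and for neurons in general, 12 of 35 and 7 of 18 listed genes could be named, all selected by the authors at 2-fold or more, which sets the lower end of their folds. The RIM gene unc-10 stood at 11.50 ± 0.18 (SD, n = 4) in DD neurons and 5.10 ± 0.49 (SD, n = 3) in all cells, a log2 difference of 6.40 ± 0.24 (adjusted p = 8.47e-05). All 12 named genes for synaptic vesicle release and recycling were higher in every DD array than in any all-cell array, and 3 passed over all probe sets. These were unc-10, the dynamin gene dyn-1 at 3.01-fold (1.59 ± 0.24, adjusted p = 0.0454) and the presynaptic kinase gene sad-1 at 2.16-fold (1.11 ± 0.17, adjusted p = 0.0466). The syntaxin gene unc-64 (log2 difference 1.00), the SNAP-25 gene ric-4 (1.01), unc-18 (1.01), the synaptojanin gene unc-26 (1.02), ehs-1 (1.03), sng-1 (1.15), unc-41 (1.24) and the clathrin adaptor gene unc-11 (1.28) did not pass over all probe sets. Among 7 named pan-neuronal markers, unc-10 alone passed over all probe sets, though all 7 were higher in every DD array than in any all-cell array. The named member of the neuropeptide processing list, unc-31, had a log2 difference of 1.04 and an adjusted p of 0.128. Neither list was shown to differ from the other named genes by camera, with adjusted p of 0.788 for pan-neuronal and 0.874 for synaptic genes. The medians, 1.04 and 1.07, lay below those of the other named genes, while unc-10 raised the means to 1.84 and 1.57. The camera direction was upward for the pan-neuronal and downward for the synaptic list. Listed and other named genes alike were selected as higher, so camera does not address enrichment over all genes on the array.

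Among channels and receptors, 5 genes of the TWK family of potassium channels could be named. Of these twk-12 (4.72-fold, log2 2.24 ± 0.31, adjusted p = 0.0344) and twk-7 (2.89-fold, 1.53 ± 0.18, adjusted p = 0.0209) passed over all probe sets. Their all-cell levels, 4.61 and 4.73, lay below the medians of the all-cell arrays, so both folds are not exact. The values of twk-30 (2.14), twk-23 (2.05) and twk-43 (1.26) did not pass over all probe sets. The list's median was 2.05 against 1.24 for the other named genes, a difference that camera did not establish (adjusted p = 0.142). The nicotinic receptor subunit gene acr-9 had a log2 difference of 1.64 (adjusted p = 0.148), and the neuropeptide gene flp-15 had 1.23 (adjusted p = 0.105). Of the axon guidance genes none of the 3 named ones passed over all probe sets: syg-1 (1.14), unc-76 (1.09) and the ankyrin gene unc-44 (1.02, adjusted p = 0.221, camera adjusted p = 0.342 for the list). In the list of immunoglobulin-type proteins oig-1 was higher and syg-1 was not called.

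Other genes with large folds have varied roles. Those named by the rule were C13A10.2 (now nssp-12, 9.58-fold, adjusted p = 0.00937), F52H2.4 (now smvt-1, 7.15-fold, adjusted p = 0.0251), the lysozyme gene ilys-4 (6.42-fold, adjusted p = 0.0251), C06E7.2 (6.13-fold, adjusted p = 0.0377), the basement membrane collagen gene cle-1 (5.83-fold, adjusted p = 0.00937) and Y64G10A.7 (5.78-fold, adjusted p = 0.00937). Chosen after their values were seen, F53B6.2 (now madd-4), a secreted organiser of neuromuscular synapses, was 5.59-fold higher (adjusted p = 0.0251), the amino acid transporter gene aat-3 was 4.30-fold higher (adjusted p = 0.0121), and nsf-1, whose product takes SNARE complexes apart, was 2.63-fold higher (adjusted p = 0.0342).

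Small heat shock protein and Hsp70-type genes had large differences too. Of 10 named genes in the heat shock list, 2 passed over all probe sets: the small heat shock gene hsp-16.41 at 27.1-fold (4.76 ± 0.61, adjusted p = 0.0263) and the Hsp70-family gene F44E5.4 at 11.8-fold (3.56 ± 0.54, adjusted p = 0.0456). The all-cell level of hsp-16.41, 3.70 ± 1.18 (SD, n = 3), lay near the 25th percentile of the all-cell arrays (3.58 to 3.65), so it was not shown to be above background and its fold is not exact. In all 10 every DD array lay above every all-cell array, as in 222 of the 236 listed probe sets. The values of F44E5.5 (3.78), hsp-16.2 (3.51), hsp-70 (3.21), hsp-16.49 (2.74), hsp-16.1 (2.53), C30C11.4 (now hsp-110, 2.10), dnj-13 (1.71) and dnj-8 (1.45) did not pass over all probe sets. The list's median was 2.98 against 1.24 for the other named genes (camera adjusted p = 1.15e-04), and with an estimated correlation the adjusted p was 0.384. The pairs F44E5.4 and F44E5.5 and the hsp-16 genes are related in sequence, and 6 of the 10 probe sets are marked as matching several transcripts, so their separate values are uncertain. The call of hsp-16.41 was lost whichever array was left out (adjusted p 0.0587 to 0.0861), and that of F44E5.4 unless it was all cells replicate 1 or 3 (0.0448 to 0.160 over the 7 arrays).

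**Figure D3:**
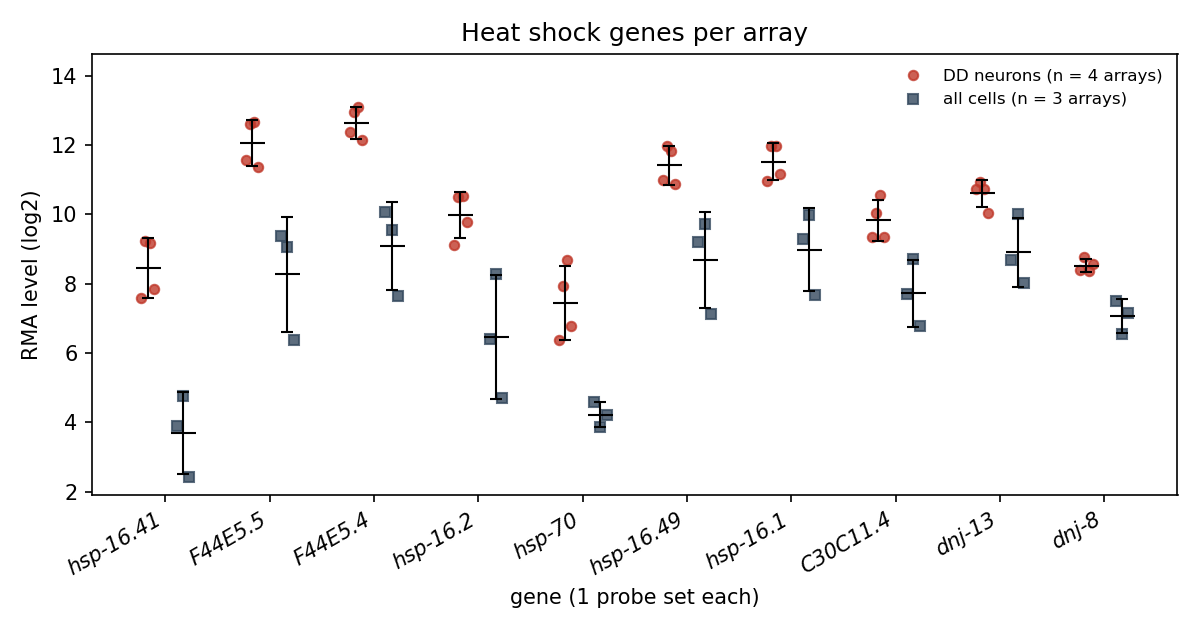
RMA levels (log2, y axis) of the 10 named heat shock genes (x axis) on each DD array (red circles, n = 4) and all-cell array (dark squares, n = 3), with horizontal bars for the mean and whiskers for 1 SD. DD arrays lie above all-cell arrays for all 10 genes, and the all-cell arrays spread widely, with an SD of 1.79 for hsp-16.2.

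Markers of other tissues were few among the named genes. The pharynx list took the pqn family whole, though not every member is pharyngeal. The named gene of that list, pqn-44 (now tent-5), was 2.35-fold higher (log2 1.23 ± 0.18, adjusted p = 0.0377). The other 4 did not pass: the intestinal acyl-CoA dehydrogenase gene acdh-1 (log2 1.86, adjusted p = 0.189), the titin gene ttn-1 of muscle (1.18, adjusted p = 0.134, with 3 probe sets from 1.18 to 2.11), the P granule gene pgl-1 (1.07, adjusted p = 0.224) and the epidermal-list gene ptr-24 (1.03, adjusted p = 0.0973). Markers of a tissue that were lower in DD neurons could not be named here, so the purity of the sorted cells was not measured.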

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

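The tests by splits of the arrays, of the heat shock genes, of unc-10 and of the array controls as a set were chosen after the results had been seen. Among 73 named genes whose 4 DD arrays were examined for a single distant array, 3 had one, where chance gives about 1 in 20. For unc-25, DD replicate 2 read 10.84 while the other 3 DD arrays read 11.39 to 11.46 (log2). For pld-1, DD replicate 4 read 7.97 while the others read 8.47 to 8.54. For smc-4, DD replicate 4 read 7.55 while the others read 8.07 to 8.13. The array controls, left out of the main tests, were higher in DD neurons as a set, with a mean level of 5.85 ± 0.13 (SD, n = 4) against 5.49 ± 0.09 (SD, n = 3) and a difference of 0.357 (log2, exact two-sided permutation p = 0.0286, the smallest the design can give). Probe sets for worm genes, such as actin, Gapdh and ubiquitin, are among these controls, several for each gene. A technical shift and a difference in these genes were therefore not told apart. Of the 77 control probe sets, which are not all separate controls, 75 were higher, with a median difference of 0.34 against 0.06 for all tested probe sets. None passed limma's threshold (smallest adjusted p 0.149), and of 20 at an unadjusted p under 0.05, 19 were higher.

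By limma, of the 35 splits of the 7 arrays into 4 and 3, only 1, the real one, called as many as 43 higher. Only 1 called as many as 51 lower, and 0 was the highest of the other splits in each direction. That share is the smallest 35 splits can give, and a split that mixes the groups also widens the spread within them. The real grouping thus ranked first, but the splits do not exclude chance for the counts of called probe sets. For the authors' score and at least 2-fold, direction was first taken toward the side that holds the larger share of DD arrays. Only the real split, 1 of 35, then reached 236 higher probe sets, and 1 of 35 reached 580 lower, the highest other giving 346. This turning uses the true groups, so these shares are not a test of chance. Without turning the direction, 3 of the 35 splits gave as many as 236 on the side of 4 arrays. The 2 others, with 346 and 313, set the 3 all-cell arrays and DD replicate 2 or 4 against the remaining DD arrays, so they count probe sets lower in DD neurons. For both directions together 816 stood against 461 in the highest other split, 346 of these lower in DD neurons and the rest higher.

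Of the 10 named heat shock genes 2 passed limma's threshold over all probe sets. The levels of the 10 moved together within a group, with a mean pairwise correlation of deviations from the group means of 0.561. In 10000 random sets of 10 other named genes the 95th percentile was 0.180. The 7 co-regulated D-type identity genes also moved together (0.400 against 0.221), so this does not favour handling stress over any other source, and copies that share probes would raise it too. Without all cells replicate 3 the list's mean was still 2.385 ± 0.430 SE higher in DD neurons. Every DD array (9.75 or more) lay above all cells replicates 1 and 2 (7.67 and 8.05). These genes had been selected as higher on the same arrays, and each was separated on them. That order was therefore fixed in advance, and it does not test whether a low all cells replicate 3 was the cause. For the excess over the other named genes, 1.48 ± 0.61 SE over all arrays and 0.904 ± 0.477 SE without that array (medians 2.29 against 1.31, camera adjusted p = 2.06e-04 with the preset correlation, while over all arrays an estimated one gave 0.384), a low array was not excluded. Stress from preparing the DD cells and a level set by the DD cell type both stay open as hypotheses, since the labels do not give how the all-cell samples were prepared.

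The gene unc-10 lay far above the other named pan-neuronal genes. It exceeded the next of them, unc-11, by 5.12 ± 0.39 SE on the log2 scale. An equal shift of such genes, by enrichment of neurons as a class, does not give that gap. Whether enrichment shifts such genes equally was not tested, and the gap itself prompted the question, so no conclusion on enrichment is drawn. A candidate explanation is unc-10 sequence carried by the transgene of the sorted strain, such as part of its untranslated region; only 1 unc-10 probe set could be named and the construct's sequence was not analysed here, so this cannot be told apart from high unc-10 expression in DD neurons.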

How the results depend on the processing

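The alternative with the authors' score was added after the data were seen. Among 73 named genes, 997 values under alternatives gave 824 on the same side of the threshold, 151 no longer past it and 22 newly past it, none with a changed sign. Against 43 higher and 51 lower probe sets, the dimmest probe sets dropped gave 82 lower, another quantile normalization 33 lower, probe sets matching 1 transcript 29 lower (fewer tested), an adjusted p under 0.01 gave 14 higher and 1 lower, and the authors' score 236 higher and 580 lower. Welch's test with adjustment gave 0 higher and 0 lower, with 2133 at an unadjusted p under 0.05. Overlap with the authors' list equalled the higher count for these, 14 and 0. With 1 array left out (fewer arrays), higher probe sets and the overlap ranged from 6 to 23, lower ones from 0 to 39. Same-numbered arrays deviated with correlations of -0.005, 0.070 and 0.086, and differently numbered ones with -0.19 to 0.15. With so few arrays, pairing by number was neither shown nor excluded. A replicate block in limma gave 2 higher (1 of them among the 43), 0 lower (2075 at an unadjusted p under 0.05) and an overlap of 2. The median correlation within groups was 0.967 and became 0.943 without dim probe sets. With an estimated correlation the identity list (median 2.92) had an adjusted p of 0.0909 and the heat shock list (2.98) one of 0.384; without cross-matching probe sets the heat shock list had a median of 2.80 and an adjusted p of 0.130. By fry the pan-neuronal (1.04), synaptic (1.07), axon guidance (1.09) and potassium channel (2.05) lists passed, but these genes were selected as higher. Scaling to the 75th percentile moved the median of all probe sets by 0.109 (log2). Apart from these constructions the cause was not tested. Scaling to ribosomal proteins and a list test over the whole array were not run.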

Other observations

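The test of neighbouring genes was chosen after the data had been seen, and the test of chromosome IV before. The genes in the first 2 paragraphs were chosen after their values were seen and stand for no common theme. The retromer gene vps-35 was higher in DD neurons (log2 difference 1.22, limma adjusted p = 0.0397), as were the phospholipase D gene pld-1 (1.82, adjusted p = 0.0251, with another probe set at 1.05 not called), the stomatin-type gene sto-2 (1.94, adjusted p = 0.013), atgp-1 (1.66, adjusted p = 0.00937), the neuronal migration gene mig-13 (1.20, adjusted p = 0.0365) and set-26 (1.11, adjusted p = 0.0392). The RIM-binding protein gene tag-168 (now rimb-1, 1.14), the neuropeptide gene nlp-13 (1.09), the cadherin gene hmr-1 (1.40), the ligand-gated channel gene lgc-50 (1.56) and the transcription factor genes fozi-1 (2.17) and mab-9 (1.85) did not pass.

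Other genes on the authors' deposited list that did not pass limma's threshold were smc-3 (log2 difference 1.12), smc-4 (1.07), mix-1 (1.12) and the Argonaute gene csr-1 (1.22), as well as acs-2 (1.96), sodh-1 (now adh-1, 1.24) and gei-7 (now icl-1, 1.31). The gene Y53G8AM.5 (now nspg-7.2) had one of the largest differences, 4.60 ± 0.77 SE, with an adjusted p of 0.0571.

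Probe sets at least 2-fold lower in DD neurons were more numerous than those at least 2-fold higher, 927 against 349. The 3′ minus 5′ difference of the catalase control was 0.640 ± 0.954 (SD) in DD neurons and 2.69 ± 0.322 (SD) in all cells (exact two-sided permutation p = 0.0571, adjusted 0.286 over 5 controls). Catalase was the most distant of the 5, at -2.05 for DD neurons minus all cells. The same value was -0.005 for actin, -0.204 for Gapdh, -0.130 for gly14 and -0.340 for ubiquitin.

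Named genes lay close together in the genome more often than chance placement gives. Of 196 genes placed on the assembly WBcel235, 26 had another named gene among the 2 nearest protein-coding genes on either side, in 13 pairs, against a median of 8 and a 95th percentile of 14 in 10000 random draws. The pairs include hsp-16.2 with hsp-16.41, F44E5.4 with F44E5.5, and F52H2.4 with aat-3. The largest of these draws gave 23. Without the heat shock genes 18 of 186 remained, against a 95th percentile of 13 and a largest draw of 26, so the excess was weaker. The draws came from all protein-coding genes, not from those on the array. The placed genes were also spread unevenly. Chromosome III held 21.94% of them against 13.23% of all protein-coding genes, and V held 17.35% against 25.01%. Variants linked to the reporter insertion on chromosome IV may raise neighbouring genes there, but IV held 15.3% of the placed genes against 16.43% of all protein-coding genes (exact binomial p = 0.772), and 1 of the 13 pairs, which argues against that as the whole cause. Shared regulation of neighbours in DD neurons stays open and was not tested.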
